A study of Drosophila melanogaster
Mus musculus with 6 samples.

How the data were processed

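The samples were C3H10T1/2 cells expressing tagged WT or K36M histone H3.1, each as H3K36me2 immunoprecipitate, H3K27me3 immunoprecipitate and input, 1 sample per group. Group membership came from sample titles and genotypes. The titles of both inputs named H3.3 while their genotypes named H3.1, and the genotype was used. Inputs were not analysed here, because the table used had no input columns, and neither was H3K36me3, for which the protocol lists an antibody. Per the labels' protocols, cells were lysed and digested with micrococcal nuclease to mononucleosomes, soluble Drosophila S2 chromatin amounting to 5% of the mouse chromatin was added before immunoprecipitation, and libraries followed an Illumina TruSeq protocol. Another label states that mouse and fly cells were mixed in equal parts; the labels do not settle which ratio was used. Per the submitters' processing notes, Bowtie 1.0.0 and the builds mm9 and dm6 were used. Counting, duplicate removal and read filters are not given in the sources used here.

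The deposited table holds a signal value per genomic interval for each of the 4 immunoprecipitated libraries, as scaled coverage made by the authors. In every library 100% of values were whole multiples (within 0.01 of a read) of 1 step, 0.636 for H3K36me2 in WT, 0.078 for H3K36me2 in K36M, 0.109 for H3K27me3 in WT and 0.295 for H3K27me3 in K36M, so the reads behind each value were recovered by division. The step is taken to carry the spike-in scaling; how it was computed is not given in the sources used here, and no fly reads are in the table to check it. Any error in the factor multiplies every bin of a library alike, and reads from unenriched chromatin are multiplied with the rest. The end of chromosome 1 at 197195432 is that of mm9, and coordinates are 1-based in that build.

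Of 253926 intervals, 249267 were 10 kb wide. Wider intervals appeared to hold sums: the 3881 of 20 kb had a median of 2.02 times the H3K36me2 value of their 10 kb neighbours (interquartile range 1.73 to 2.37). All 4659 intervals of other widths were left out, as were 322 of 10 kb without signal in any library, which left 248945 bins. This last filter replaced a planned one on input. Runs of bins therefore end at each wide interval. The median bin held 151 reads for H3K36me2 in WT, 79 for H3K36me2 in K36M, 54 for H3K27me3 in WT and 99 for H3K27me3 in K36M, which gives 95% counting half-widths of 16.0%, 22.1%, 26.7% and 19.7% (normal approximation). Ratios of summed reads carry 95% counting intervals from the binomial split of the reads of both libraries.

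Genome-wide levels were compared as the ratio of mean scaled reads per bin. Per bin, log2 ratios of K36M over WT were taken after adding a pseudocount, the 5th percentile of WT values above 0 (19.7 for H3K36me2 and 1.64 for H3K27me3). They understate changes in bins near or below the pseudocount, and the H3K36me2 pseudocount exceeds the K36M median of 6.16. A bin passed the rule of size at a change of at least 2-fold if its mean over both lines was at or above the 25th percentile. The regions named, by a rule set before the data were examined, are the 6 runs of adjacent passing bins spanning at least 50 kb with the largest mean log2 ratio, per mark and direction; 2 runs qualified for higher H3K36me2 and 4 for lower H3K27me3. Regions are given by position alone, since no mouse gene annotation was used here, and the gene lists written for named genes were not applied. Relations across bins are Spearman's rho, with their range over the 19 autosomes and X. Deciles, chromosome medians and shares of signal in the top bins were computed from scaled reads.

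Counting noise alone was simulated for all bins, with no difference between the lines. It gave a standard deviation of the log2 ratio of 0.13 for H3K36me2 and 0.16 for H3K27me3, against 1.13 and 1.02 observed, and 0 bins past the rule. On simulated data for the H3K36me2 comparison, 462 of 490 bins changed 3-fold were called (94.3%) and 0 of 495 changed 1.4-fold. For H3K27me3 these were 462 of 490 and 0 of 500. Both lines were simulated at the same library total, and changes were made only in bins above the lowest levels and without extreme read numbers. The rates called therefore do not apply to bins whose H3K36me2 lies near or below the pseudocount, as most do in K36M. Alternatives fixed before the data were examined were another pseudocount, other level filters, a 1.5-fold rule, centring, scaling to library totals, averaging of 5 adjacent bins, other rankings and coefficients, and autosomes alone. Background subtraction, removal of extreme bins, inclusion of wide intervals, and autosomes alone for counts of bins were added after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.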

Results

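Histone marks were mapped in C3H10T1/2 cells, mesenchymal progenitors derived from mouse embryos of the C3H strain. A pair of lines was compared: cells stably expressing FLAG-HA-tagged wild-type histone H3.1 (WT) and cells stably expressing the same tagged histone with methionine in place of lysine 36 (K36M). Chromatin immunoprecipitation with sequencing was made for H3K36me2, a mark of broad euchromatic domains, and for H3K27me3, the mark deposited by Polycomb repressive complex 2. Chromatin of Drosophila S2 cells was added as an external reference (ChIP-Rx), so that global changes in a mark could be measured. The series held 6 samples, 1 per mark or input and line, and the table used here covered the 4 immunoprecipitated libraries in genomic bins of 10 kb. The values were reads multiplied by 1 factor per library, called scaled reads below. Recovered read totals were 59618463 for H3K36me2 in WT, 51982053 for H3K36me2 in K36M, 31847430 for H3K27me3 in WT and 29817968 for H3K27me3 in K36M. With 1 library per group there were no replicates, so no test between the lines was possible and no p-value is given. Intervals are 95% intervals for counting error only, and reads without molecular identifiers are not independent molecules.

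The first question was how far each mark changed over the genome when K36M histone was expressed. H3K36me2 was lower in K36M almost everywhere: the mean fell from 148 to 15.7 scaled reads per bin, a ratio of 0.106 (0.1058 to 0.1059), which is 9.44-fold lower. Medians fell from 96.0 (interquartile range 34.3 to 219) to 6.16 (4.76 to 10.4). H3K27me3 moved the other way, from a mean of 13.7 to 34.5 scaled reads per bin, a ratio of 2.52 (2.514 to 2.516), and from a median of 5.89 (3.16 to 16.1) to 29.2 (16.5 to 47.5). Across 248945 bins, H3K36me2 was below its WT value in 97.8% and H3K27me3 was above it in 94.6%. Chromosome by chromosome, over the 19 autosomes and X, the ratio of means ranged from 0.0810 to 0.131 for H3K36me2 and from 2.08 to 3.16 for H3K27me3.

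The size of both shifts was set by the library factors in the table. Unscaled reads in K36M were 0.863 of those in WT for H3K36me2 and 0.929 for H3K27me3, whereas the factors differed 8.15-fold (lower in K36M) and 2.71-fold (higher in K36M). The median log2 ratio of all bins was -1.62 for H3K36me2 and 1.60 for H3K27me3 with the factors, and 0.04 and 0.46 when each library was scaled to its own total. Values below use the deposited factors unless scaling to library totals is named.

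**Figure D1:**
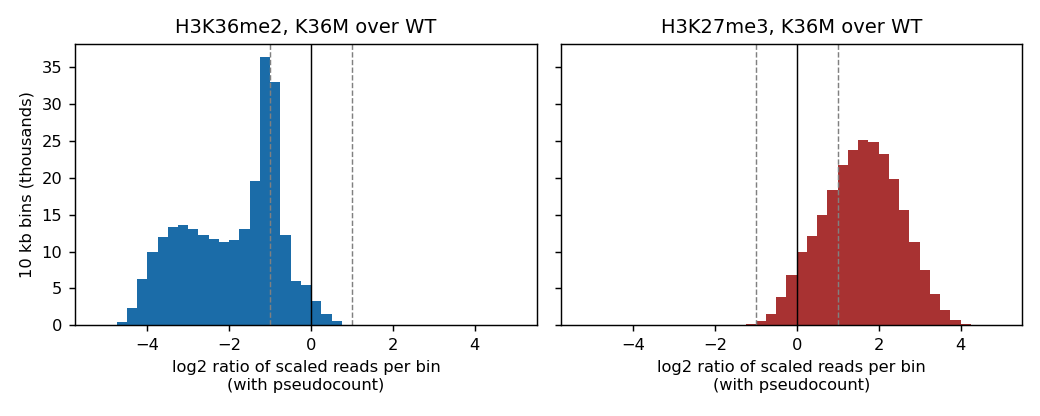
Histograms of the log2 ratio of K36M over WT in 248945 bins of 10 kb, for H3K36me2 and H3K27me3, with the number of bins on the vertical axis and dashed lines at 2-fold. H3K36me2 ratios lie almost wholly below 0 with a median of -1.62, and H3K27me3 ratios lie mostly above 0 with a median of 1.60.

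The named regions of H3K36me2 loss carried high H3K36me2 in WT. The region ranked first was on chromosome 16 at 25630001 to 25770000 (mm9), where the mean dropped from 569 to 6.64 scaled reads per bin, 85.7-fold lower (80.8 to 91.0). A neighbouring stretch at 25790001 to 25940000 was 72.9-fold lower. On chromosome 15, the stretches 60950001 to 61060000, 61140001 to 61230000 and 61250001 to 61320000 were 75.5-fold, 75.3-fold and 71.5-fold lower. The longest of the 6 named domains, on chromosome 10 at 36860001 to 37320000, covered 460 kb and went from 557 to 8.56, 65.0-fold lower. H3K27me3 was low in WT in all 6, at 4.43 to 5.67 scaled reads per bin, and was 8.20-fold to 13.3-fold higher in K36M, reaching 45.8 to 59.1. Scaled to library totals, H3K36me2 in K36M was 0.110 to 0.145 of WT in these regions. Their K36M values of 6.64 to 8.56 lay near the K36M genome median of 6.16. Unenriched reads may make up part of them, which could not be measured without input columns. The pseudocount limits the fall that bins with low WT values can show, so the ranking favours regions with high values. By a rule of size, a fall of at least 2-fold on the log2(value + 19.7) scale in bins at or above the 25th percentile of the mean level, H3K36me2 was lower in 167632 of 186769 bins (89.8%). Of these bins, 106254 were lower by at least 4-fold, and 7366 uninterrupted runs spanned 50 kb or more, the longest 2590 kb. When log2 ratios were centred at their median, 77516 bins were lower and 13252 higher; without centring, the count of lower bins ran from 100926 to 186852 over the alternatives.

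Gains of H3K36me2 were rare: 33 bins in 13 runs on 7 chromosomes rose past the same rule, and 2 runs reached 50 kb. On chromosome 4 at 23220001 to 23280000, H3K36me2 rose from 32.3 to 156 scaled reads per bin, 4.82-fold (4.30 to 5.42). On chromosome 10 at 102970001 to 103030000 it rose from 35.3 to 143, 4.05-fold (3.63 to 4.53). Scaled to library totals, these ratios were 45.6 and 38.3. H3K27me3 in these regions was low in WT, at 3.67 and 3.27, and reached 16.3 and 9.39 in K36M, both under the K36M genome median of 29.2. The count of gains was sensitive to the settings and, without centring, ran from 4 bins with the median level as pseudocount to 884 after background subtraction, a setting chosen after seeing the data.

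**Figure D2:**
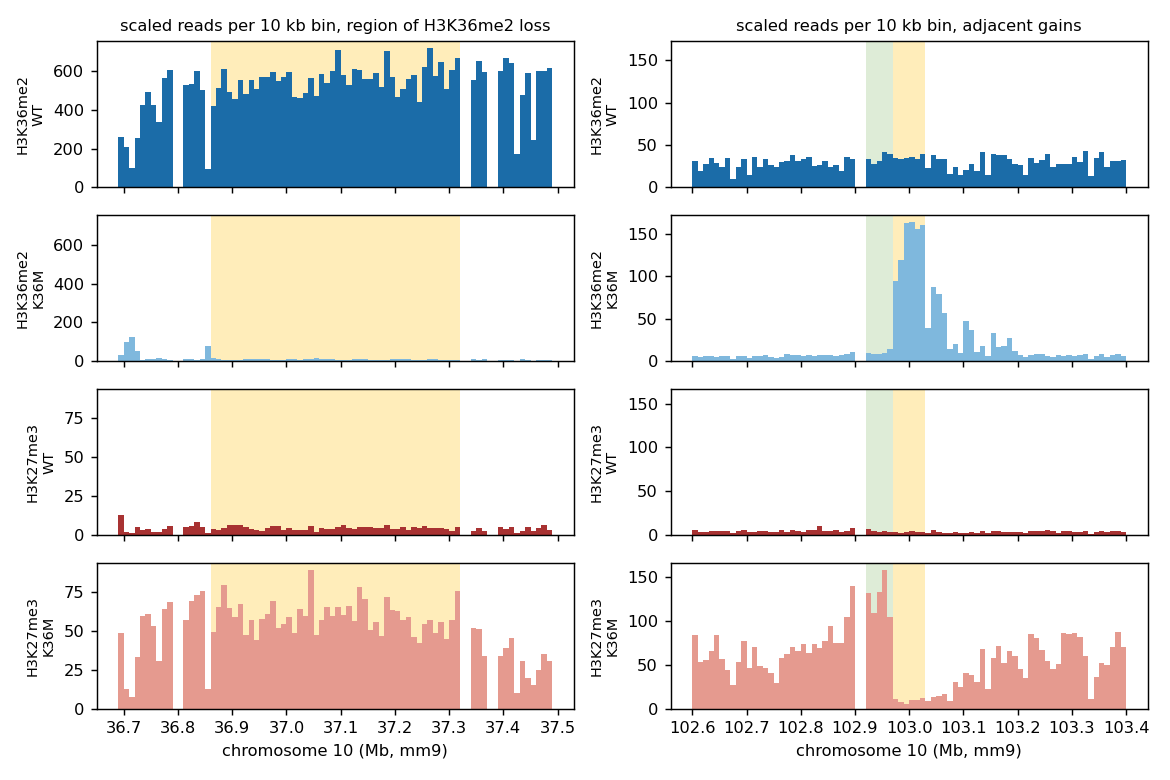
Scaled reads per 10 kb bin in the 4 libraries in windows of chromosome 10, with positions in Mb (mm9). Left, yellow shading marks the region of H3K36me2 loss, where means went from 557 in WT to 8.56 in K36M; right, yellow marks the region of H3K36me2 gain (35.3 to 143) and green the adjoining region of H3K27me3 gain (4.32 to 128). Both libraries of a mark share a vertical scale, and white gaps are intervals wider than 10 kb, which were left out.

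The 6 named gains of H3K27me3 lay in regions below the WT median of 5.89, and ranking by ratio favours such regions. The largest of them was on chromosome 10 at 102920001 to 102970000, which ends where the H3K36me2 gain on that chromosome begins: H3K27me3 went from 4.32 to 128 scaled reads per bin, 29.6-fold higher (25.6 to 34.4). H3K36me2 there went from 34.3 to 9.98, a fall with the deposited factors but a ratio of 2.75 when each library was scaled to its own total. Chromosome 13 at 111430001 to 111710000 rose from 3.95 to 78.7 (19.9-fold) and chromosome 1 at 81760001 to 82180000, 420 kb long, rose from 4.03 to 75.1 (18.7-fold), with H3K36me2 falling from 523 to 18.8 and from 572 to 8.73. Chromosome 12 at 80530001 to 80660000, chromosome 1 at 164030001 to 164150000 and chromosome 13 at 32310001 to 32400000 rose 22.6-fold, 18.2-fold and 20.8-fold. Scaled to library totals, the 6 gains were 7.24-fold to 11.8-fold. In 5 of the 6 named gains, all but the one on chromosome 10, WT H3K36me2 was between 375 and 572 scaled reads per bin, far above the genome median of 96.0.

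Losses of H3K27me3 were few, and the 4 that spanned 50 kb or more lay in regions with high H3K27me3 in WT, which selection by a fall favours. Chromosome 15 at 55990001 to 56060000 fell from 48.8 to 16.1 scaled reads per bin, 3.03-fold lower (2.73 to 3.38). Chromosome 6 at 98090001 to 98190000 fell from 64.1 to 25.5, chromosome 4 at 100360001 to 100410000 from 39.8 to 16.1, and chromosome 14 at 117230001 to 117290000 from 46.4 to 19.3. Scaled to library totals, H3K27me3 in K36M was 0.131 to 0.166 of WT in these 4 regions. These regions lost H3K36me2 too, from 61.1 to 112 scaled reads per bin in WT to 4.49 to 5.15 in K36M. By the rule of size, on the log2(value + 1.64) scale, H3K27me3 was higher in 130943 of 186720 bins (70.1%) and lower in 300. Centred at the median log2 ratio, the split was 34198 higher and 35807 lower. Without centring, the alternatives gave 77402 to 180454 bins higher and 100 to 1923 lower.

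Strong H3K27me3 bins rose less than other bins or did not rise, depending on the line used to rank them. In the top 1% of bins by mean H3K27me3 of both lines, the median log2 ratio was -0.02, against 2.00 in the middle 50% of bins, a difference of -2.02. Ranked by K36M alone, the median of the top 1% was 0.71, still below that of the middle bins at 1.90. Ranked by WT alone, the top 1% went from a median of 102 to 91.5 scaled reads per bin, while the lower 50% of bins went from 3.16 to 18.3. Scaled to library totals, the ratios of these medians, K36M over WT, were 0.356 and 2.30. The signal spread out accordingly: the top 1% of bins of each library held 8.78% of H3K27me3 in WT and 4.59% in K36M, and the top 5% held 27.8% and 14.5%. These shares do not depend on the library factors, but a difference in enrichment between the libraries could change them and was not tested. H3K36me2 became more concentrated, with 7.55% in the top 1% of bins in WT and 10.5% in K36M. A single bin on chromosome 2 held 2.50% of the H3K36me2 reads in WT and 1.31% in K36M, and this share was not recomputed without extreme bins.

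For H3K36me2, the contrast by level depended on the line used to rank bins. In the top 10% of bins by mean level the median log2 ratio was -3.90, against -1.74 in the middle 50%, a difference of -2.16. In the top 10% of bins by K36M level the median was -0.63, against -2.10 in the middle 50%, so the difference reversed to 1.47. Bins with the most H3K36me2 in WT and bins with the most in K36M were thus ordered differently, and Spearman's rho between the lines was 0.60 for H3K36me2 and 0.72 for H3K27me3 across bins.

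The second question was whether H3K27me3 rose where H3K36me2 fell. Over the whole genome the relation between the log2 changes was weak, with Spearman's rho of -0.08 across 225981 bins, from -0.26 on chromosome 13 to 0.11 on X, and negative on 16 of 20 chromosomes. It differed by the starting level of H3K36me2. In bins above the WT H3K36me2 median rho was -0.30 (-0.40 to -0.21 over chromosomes, negative on 20 of 20). In the other bins rho was 0.46 (0.34 to 0.57, negative on 0 of 20). Median K36M H3K36me2 in the lowest 4 deciles of WT H3K36me2 was 3.28 to 5.77, below the pseudocount of 19.7. The H3K36me2 log2 change in those deciles therefore largely follows the WT level, and the positive rho cannot be read as a relation to loss alone. From the sixth decile up, median K36M H3K36me2 was 7.88 to 8.81, also below the pseudocount. Median WT H3K27me3 fell there from 10.2 in the sixth decile to 5.78 in the highest. The negative rho thus cannot be read as a relation to loss alone either. At matched WT levels of both marks, autosomal bins that lost more H3K36me2 had the larger median H3K27me3 rise in 17 of 30 groups of bins in the upper 6 deciles of WT H3K36me2, with a median difference of 0.03 on the log2 scale, and in 3 of 20 groups in the lower 4 deciles, with a median difference of -0.23. By quintile of WT H3K27me3, lowest first, the upper deciles had 6, 4, 1, 1 and 5 such groups of 6. The differences were 0.16 to 0.54 in the lowest quintile and -0.03 to 0.06 in the highest. In quintiles 3 to 5 the groups had median K36M H3K36me2 of 5.38 to 8.35, below the pseudocount. The measured loss could differ little within those groups beyond the WT level, so the count of 17 cannot settle the question. By the rule of size, H3K27me3 rose in 65.4% of bins with lower H3K36me2 and in 72.3% of the others, but the others were few, since 145031 of 147508 bins tested for both marks had lower H3K36me2. Bins are not independent replicates, so these values describe the libraries.

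Across deciles of WT H3K36me2, the rise of H3K27me3 was smallest in the middle and largest at the top. In the highest decile, median H3K36me2 fell from 414 to 8.66 and median H3K27me3 rose from 5.78 to 46.3, with a median log2 ratio of 2.62. In the fifth decile H3K36me2 fell from 76.3 to 6.55, and H3K27me3, already at 16.4 in WT, reached 30.1, with a median log2 ratio of 0.78. In the second decile H3K36me2 fell from 28.0 to 4.76 and H3K27me3 rose from 4.36 to 24.8, with a median log2 ratio of 1.95. Scaled to library totals, the ratio of H3K36me2 medians turned to between 1.17 and 1.62 in the lowest 4 deciles and was 0.197 in the highest. On that scale the ratio of H3K27me3 medians turned to 0.732 in the fifth decile and 0.870 in the sixth and was 3.19 in the highest. The levels of both marks in WT were related without a single direction: median WT H3K27me3 was 2.94 scaled reads per bin in the lowest decile of WT H3K36me2, 16.4 in the fifth and 5.78 in the highest. A rank correlation does not capture such a hump, and rho over all bins was 0.11 in WT and 0.06 in K36M. Within chromosomes rho ranged from -0.10 to 0.61 in WT and from -0.32 to 0.61 in K36M, highest on X in each line.

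**Figure D3:**
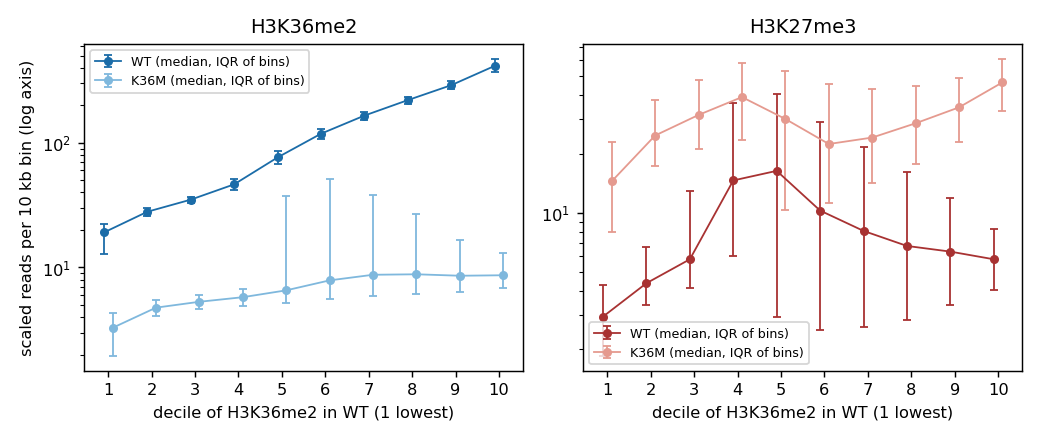
Medians (points) and interquartile ranges (bars) of scaled reads per 10 kb bin in WT and K36M, on log axes, by decile of WT H3K36me2, for H3K36me2 (left) and H3K27me3 (right). Median H3K36me2 in K36M lies between 3.28 and 8.81 in every decile, with upper quartiles of up to 51.1 in the sixth, and H3K27me3 in K36M reaches its highest median, 46.3, in the highest decile.

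The X chromosome stood apart in WT. Its median H3K27me3 was 16.9 scaled reads per bin, against 4.25 to 7.68 on the 19 autosomes, and its median H3K36me2 was 38.2, against 61.1 to 174. In K36M, X remained above the autosomes in H3K27me3, at 40.7 against 22.4 to 36.3, and its H3K36me2 median of 5.30 lay within their range of 5.15 to 7.33. Changes on X were the smallest of these 20 chromosomes for both marks, with a median log2 ratio of -1.13 for H3K36me2 (autosomes -2.47 to -1.26) and 1.11 for H3K27me3 (autosomes 1.52 to 1.96). Scaled to library totals, X changed direction, with ratios of medians of 1.31 for H3K36me2 and 0.958 for H3K27me3, while autosomes stayed at 0.372 to 0.808 and 1.85 to 2.45. Chromosome 13 had the largest fall of H3K36me2, from a median of 174 to 6.86 scaled reads per bin. On the 164 bins of Y, the median held 2 or 3 reads in each library, and no change is reported.

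**Figure D4:**
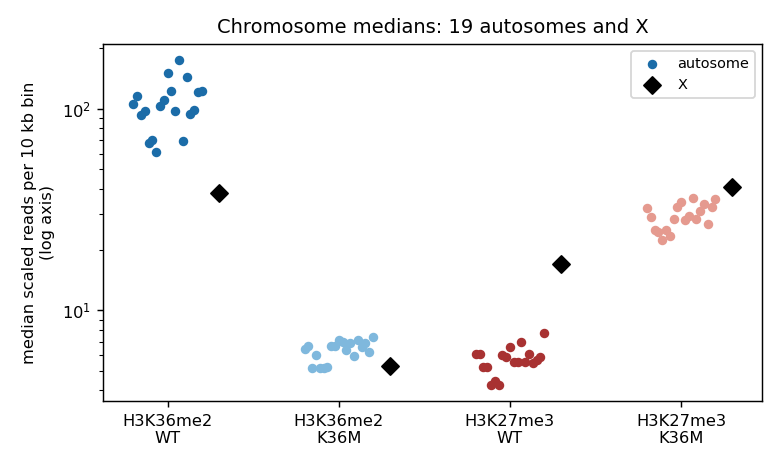
Median scaled reads per 10 kb bin of each chromosome in the 4 libraries, on a log axis; circles are the 19 autosomes and black diamonds the X chromosome. In WT, X lies below all autosomes in H3K36me2 (38.2) and above all in H3K27me3 (16.9).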

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

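Background subtraction, removal of extreme bins, addition of wide intervals and autosomes alone for the counts of bins were chosen after the results were seen; the other settings were planned. Of 85 alternative values for 11 results, 50 stayed within the spread or within 1.5-fold of the count, 34 moved further and 1 reversed. Settings based on input, and the comparison of input levels, were not run, because no input columns were used here. No leave-one-out was possible with 1 library per group, and the spread used was counting error for level ratios and the standard deviation over chromosomes for correlations and differences.

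With the median as pseudocount, bins with lower H3K36me2 numbered 100926, with higher H3K36me2 4 and with lower H3K27me3 173. A filter at the 50th percentile gave 108510 bins lower in H3K36me2 and 77402 higher in H3K27me3, from fewer bins tested. The 1.5-fold rule gave 381 bins higher in H3K36me2 and 1690 lower in H3K27me3. Centring gave 77516 lower and 13252 higher for H3K36me2, and 35807 lower and 34198 higher for H3K27me3. Averaging 5 bins gave 20 bins higher in H3K36me2 and 100 lower in H3K27me3, and background subtraction (the 5th percentile of each library) gave 884 and 1923.

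The H3K36me2 ratio of K36M over WT was 0.0642 from medians, 0.1053 on autosomes, 0.606 from medians scaled to library totals, 0.1004 after background subtraction, 0.107 without extreme bins and 0.1064 with wide intervals. The H3K27me3 ratio was 4.96, 2.56, 1.97, 2.30, 2.523 and 2.525 under the same settings. Both ratios kept their direction under each of these, but every setting except library totals keeps the deposited factors. With library totals the mean levels are equal by construction, so those ratios of medians reflect only how reads are spread over bins. The kept direction is therefore no check on the genome-wide shift. Against the ratio of means, the size moved by over 1.5 times for medians and, for H3K36me2, for medians scaled to library totals. Among medians alone, scaling to library totals moved both marks, from 0.0642 to 0.606 and from 4.96 to 1.97. Scaled to library totals, the median log2 ratio of H3K36me2 with pseudocount was 0.04, so the direction there rests on the measure used.

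The H3K27me3 difference between strong and middle bins was -1.19 when ranked by K36M, -1.53 with the median pseudocount and -2.36 after background subtraction. For H3K36me2 these were 1.47, the reversal, then -1.52 and -2.64; the ranking itself selects bins that kept H3K36me2. The share of H3K27me3 in the top bins changed by -13.3 percentage points for the top 5%. The difference in rho between marks (K36M minus WT, -0.05) became -0.36 with Pearson's r of log2 values; the cause was not tested. Counts in bins with few reads are limited by depth, least deep for H3K27me3 in WT at a median of 54 reads per bin.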

Other observations

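The tests below were chosen after the result was seen, except those of the share of X bins and of H3K36me2 loss at matched starting levels, which were set before their results were seen. The H3K36me2 signal that remained in K36M was unevenly spread. The decile of bins with the most H3K36me2 in K36M, 24912 bins, held 52.0% of the H3K36me2 signal in K36M but 13.7% in WT. In these bins the median went from 132 to 72.9 scaled reads, 1.81-fold lower, against 83.3 to 5.85 in the other bins, 14.2-fold lower. Scaled to library totals the first change is a rise of 5.23-fold. They formed 7145 runs with a median length of 20 kb, the longest 550 kb.

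The same bins were poor in H3K27me3 in both lines. Their median H3K27me3 was 2.29 scaled reads in WT and 10.3 in K36M, against 6.87 and 31.9 in the other bins. In WT, 84.3% of them lay at or below the 25th percentile of H3K27me3, and in K36M 76.9% did. By medians H3K27me3 rose 4.51-fold in these bins and 4.64-fold in the others, and the low level in K36M was a low level in WT as well. These factors do not compare gains at equal starting levels, since bins low in WT H3K27me3 tended to rise more. The lowest 2 deciles of WT H3K27me3 rose 5.23-fold and 5.77-fold by medians. Bins were selected by a value in K36M, so part of the small fall is built into the selection.

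The genome-wide fall of H3K36me2 and rise of H3K27me3 may reflect the histone mutant or an error in a library factor, and these cannot be told apart here: unscaled reads had ratios of 0.863 and 0.929, and 1 factor multiplies all bins. H3K36me2 medians were 47.8-fold lower in the highest WT decile and 5.82-fold lower in the lowest, a ratio of 8.21 against 0.925 simulated for 1 common factor, and ranked by K36M they were 1.81-fold and 7.93-fold lower, the opposite order. A single factor gives neither, but a difference in enrichment between these libraries was not tested and may contribute. The fall in the lowest decile stays open, since unscaled reads there were 1.55 times those in WT (2.05% of the K36M reads against 1.14%), and unenriched reads times a smaller factor could give it.

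The 33 bins with more H3K36me2 in K36M are a candidate for a local change. Counting noise is argued against by reads held out of the selection: 42 bins picked by the rule on a random half-sample had a ratio of 3.26 (3.08 to 3.45) in the remaining reads. Extra copies as the whole cause would multiply the K36M over WT ratio of both marks alike, by at least the 2-fold of the rule, yet for H3K27me3 it was 0.773 of the genome's ratio of medians in these bins (upper quartile 0.899). A difference between the lines other than the histone, such as clonal drift, was not tested and may remain with 1 library per group. Besides the 2 named regions, runs of at least 3 bins lay on chromosome 3 at 45030001 to 45060000 and on chromosome 14 at 95490001 to 95520000, chosen after their values were seen.

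The marks deviated in opposite directions on the WT X chromosome. More copies or better mapping of X, acting on both marks alike, is therefore excluded as the whole cause, since H3K36me2 on X was 0.370 of the autosome median. A few bins with very many reads are excluded too, since they cannot move a median and the lower quartile of X bins, 7.19, lay above the median of the autosome medians, 5.67; the share of X bins above the autosomal median, 80.7% of 15539, restates this. The labels give no sex or X status of the cells, so no biological explanation was tested.

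A hypothesis was that H3K36me2 loss leaves room for H3K27me3, so that among bins with the same WT levels of both marks those losing more H3K36me2 gain more H3K27me3. Autosomal bins of the upper 6 deciles of WT H3K36me2 were divided by quintile of WT H3K27me3 into 30 cells, each split at its median H3K36me2 change. The bins that lost more had the larger H3K27me3 rise in 17 of 30 cells, below the 25 set in advance, and the median difference was 0.03 on the log2 scale (-0.35 to 0.54). The prediction was not met as stated. In quintiles 3 to 5 of WT H3K27me3, however, the cells had median K36M H3K36me2 of 5.38 to 8.35, below the pseudocount of 19.7. The split there may rest largely on the remaining spread of WT levels and on counting noise. The count over all 30 cells therefore cannot decide the hypothesis. In the lower 4 deciles, looked at afterwards, the difference was positive in 3 of 20 cells. In the upper deciles it was positive in 6, 4, 1, 1 and 5 of 6 cells, by quintile of WT H3K27me3, lowest first. These counts followed no steady trend, but the sizes differed. The difference was 0.16 to 0.54 in the lowest quintile and only -0.03 to 0.06 in the highest. In quintiles 2 to 4 its sign varied between cells.

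A single bin took many reads in all 4 libraries: chromosome 2 at 98500001 to 98510000 held 2.50% of H3K36me2 reads in WT, 1.31% in K36M, and 0.661% and 0.879% of H3K27me3 reads in WT and K36M.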
